A study of Mus musculus with 21 samples.

How the data were processed

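RNA sequencing of mouse prostate tissue was analysed in 21 libraries, 3 in each of 7 groups. The groups, per the labels, were wild-type FVB ventral prostate, wild-type FVB anterior prostate, prostatic intraepithelial neoplasia (PIN) of Hoxb13-MYC mice taken from the ventral lobe, PIN of Hoxb13-Cre mice with floxed Pten taken from the anterior lobe, and PIN, primary tumours and lymph node metastases of the combined BMPC model. Replicates within a group were separate mice per the labels. FVB mice 1, 2 and 3 each gave both lobes, and BMPC mice 5 and 6 each gave a primary tumour and a metastasis. These shared mice were the only true pairs, and other replicate numbers that recur between groups do not mark the same animal. Ages were 12 weeks for FVB and BMPC PIN mice, 10 to 15 weeks for MYC PIN, 18 to 27 for PTEN PIN, 18 to 25 for primaries and 18 to 26 for metastases. The labels place the 3 BMPC PIN libraries in a second batch and the other 18 in the first, so batch and group cannot be told apart for BMPC PIN. Labels naming the genotype, lobe, batch and age were read from the sample records, and 0 columns were left unmatched. The description of each library named its column, except for the ventral library of FVB mouse 3, whose description repeats the column of that mouse's anterior library. It was matched by title, and its values correlated at 0.994 and 0.995 (Spearman) with the other ventral libraries and at 0.922 to 0.927 with the anterior ones.

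The deposited table held 18347 genes named by symbol. Its signal values were gene counts that the authors had divided by one size factor per library, as the values themselves showed: 100% of the values were whole multiples of the value of 1 read in their column, with a tolerance of 0.05 read and a largest deviation of 0.0046. The submitters' processing notes named mm10, CASAVA 1.8.4, RSEM 1.3.0 and DESeq2 1.30.0, without a role or an order for each, and the sources used here gave no gene annotation. Per the labels, total RNA was depleted of ribosomal RNA and sequenced as stranded paired-end libraries. The deposited values were used as they stood and are called normalized counts in the results. Whole reads were recovered from them for the tools that need counts. The sources do not say whether reads of the MYC transgene were counted to mouse Myc.

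Depth differed between groups. Recovered reads per library ranged from 21.4 to 56.7 M in wild-type ventral lobe, 34 to 55.7 M in wild-type anterior lobe, 23.5 to 70.7 M in MYC PIN and 28.7 to 56.1 M in PTEN PIN. BMPC primaries had 15.6 to 42 M and metastases 12.5 to 48.9 M, whereas BMPC PIN had 3.7 to 7.2 M. A count of 0 allows for up to 3 reads, which is 0.991 normalized counts in MYC PIN replicate 1 and 24.1 in BMPC PIN replicate 3. Folds against a group at 0 in every library were computed against this floor, per library and averaged over the group, and are given as lower bounds. A group mean under its floor but above 0, such as that of Ren1 or Glb1l3 in BMPC PIN, kept its fitted fold change. The size of such a change is uncertain.

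Genes with at least 10 normalized counts in at least 3 libraries were tested (16211 genes, with 2136 left out). The comparisons were fitted in limma 3.58.1 (R 4.3.3) on log2(value + 1), with 1 model of all 21 libraries, 14 residual degrees of freedom, a mean-variance trend and robust moderation. P values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene is called where the adjusted p was under 0.05. Every adjusted p for a gene comes from this limma model unless another tool is named. There were 10 comparisons: each PIN with the wild-type lobe of its own site, BMPC PIN with each of the other PIN groups, primary tumours with BMPC PIN and with PTEN PIN, metastases with primaries, the wild-type lobes with each other, and the difference between the MYC and PTEN effects. Model groups were compared as libraries of 3 mice against 3. Values are mean ± SD with n = 3 libraries, and fold changes are on the log2 scale.

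A set of 29 gene lists (617 genes, 597 of them in the table) covered growth, lineage, signalling, immune, stromal, metabolic, chromatin and carry-over programmes. Each list was tested with camera in limma, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 29 lists. The number of members called is given over all genes and adjusted over the list alone. A list of tuft cell genes was added after the data were seen, and its camera p values are unadjusted. Named genes followed a rule: the 8 largest increases and 8 largest decreases per comparison among called genes with a mean of at least 100 normalized counts in the higher group and no overlap between libraries, up to 4 members of each list with the lowest adjusted p, and a panel of 15 genes reported in every group. Overlap was not judged for the difference of effects. Unnamed gene models, mitochondrial genes, small RNAs and antigen receptor segments were left out of the largest changes. The groups, comparisons, lists, rule for named genes, tests and most alternatives were fixed before the data were examined.

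Pairing was checked by correlating, across genes, the residuals of libraries from 1 mouse. Correlations were 0.11, 0.03 and 0.07 for FVB mice 1, 2 and 3, 0.06 for BMPC mouse 5 and -0.20 for BMPC mouse 6. Libraries of different mice in the same groups correlated at -0.12 to 0.05 for the lobes and -0.20 to 0.21 for BMPC tumours, and genes are not independent replicates in such a check. The pairs therefore rest on the labels, and blocked fits were run as alternatives. No library duplicated another, since the smallest chi-square per degree of freedom between replicates was 15.8.

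The alternatives were other pseudocounts, filters and scalings, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, fits to the compared groups alone, library weights, a minimum fold change, blocks for mouse or replicate number, and leaving out each library. Thinning reads to the shallowest library, removing a trend with transcript length (known for 15412 tested genes), leaving out both libraries with seminal vesicle transcripts and leaving 1 library out of the list tests were added after the data were seen. Procedures were tested on simulated data with known changes. In these simulations the share of false calls by limma was 4.4% for MYC PIN against wild type, 9.3% for metastasis against primary and 18.7% for BMPC PIN against PTEN PIN, so both of the last comparisons exceeded the nominal 5%. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

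Left out were 26 gene symbols converted to dates, which stayed in the tests and held at most 0.21% of counts in any library but are never named. Symbols are those of the table. Several named genes have close paralogs between which reads are hard to assign, among them the Sprr2a, Gsdmc, Reg3 and renin genes and Amd1, and their values are those of the table.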

Results

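The models carry a MYC transgene, loss of Pten, or the combination named BMPC, and the comparisons address how each PIN lesion differs from its own lobe and how combined tumours differ from their precursor. Wild-type replicates resembled each other most, with mean Spearman correlations across genes of 0.994 in the ventral and 0.993 in the anterior lobe, against 0.969 in MYC PIN, 0.980 in PTEN PIN and 0.900 in BMPC PIN. Primary tumours correlated at 0.759 with the wild-type anterior lobe and at 0.917 with metastases.

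**Figure D1:**
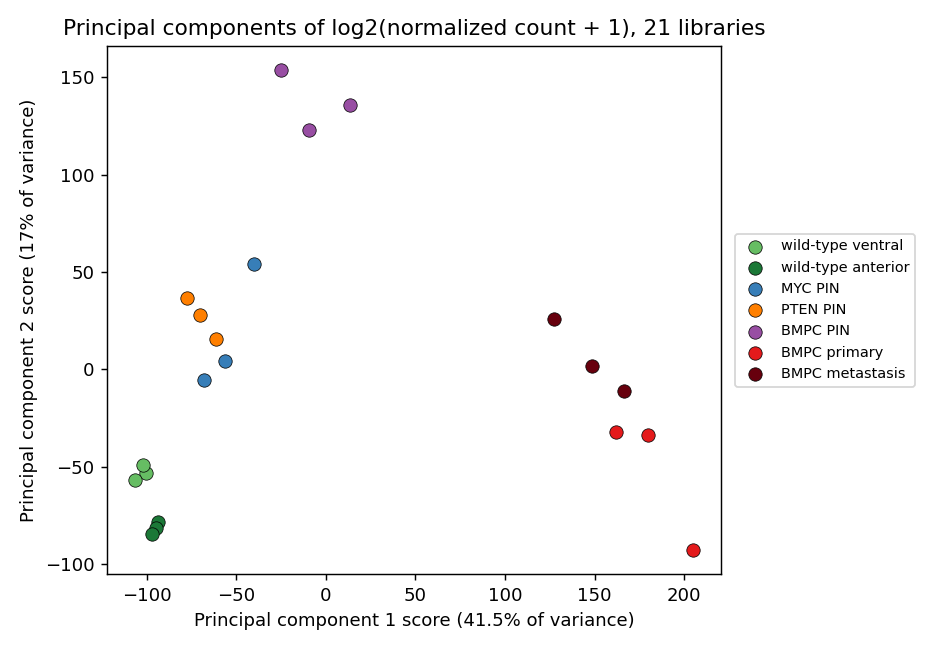
Scores of the 21 libraries on the first and second principal components of log2(normalized count + 1), with 1 point per library coloured by group. Component 1 (41.5% of variance) runs from -106.5 in wild-type ventral lobe to 205.21 in BMPC primaries, and component 2 (17%) is highest in BMPC PIN, at 123.11 to 153.86.

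Several of the largest differences between the wild-type lobes were in genes of secreted proteins. The ventral lobe was marked by spermine-binding proteins and protease inhibitors of seminal fluid, and the anterior lobe by the clotting enzyme Tgm4 and by renin. Single genes called between the lobes included Cdkn1a, which encodes a cell cycle inhibitor, and Hk2, which encodes a glycolytic kinase.

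Of 16211 genes tested, 2334 were called between the lobes, 1267 higher and 1067 lower in the ventral lobe. Sbp reached 6261876 ± 1266079 normalized counts in the ventral and 1947 ± 607 in the anterior lobe (log2 fold change 11.67), and Sbpl (11.67), Spink3 (12.00), Spink5 (11.60), Abo (10.41), Ibsp (10.62) and Msmb (10.39) were also higher. Tgm4 stood at 3250 ± 3189 in the ventral and 1862232 ± 285386 in the anterior lobe (-9.59), with Glb1l3 (-9.52), Ren1 (-9.29), Ren2 (-8.69), Serpina5 (-9.23), Gsdma (-8.56), C1rb (-9.07) and Olfm4 (-8.49) lower as well. Among 29 androgen-responsive and secretory genes 12 were higher and 2 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.00035, adjusted p = 0.96 with an estimated correlation), and Fkbp5, which encodes a steroid receptor chaperone, was higher by 4.12. Luminal progenitor genes had 8 of 18 higher, 11 adjusted over the list alone (camera adjusted p = 2.8e-05, adjusted p = 0.96 with an estimated correlation), including Cldn10 (7.11), Clu (5.11) and Krt4 (5.05). Unfolded protein genes had 7 of 22 lower and 1 higher, 9 and 1 adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.96 with an estimated correlation), such as Atf6 (-1.73), Chac1 (-3.81) and Ddit3 (-1.73). Cdkn1a (2.49), Hk2 (4.24), Btg2 (2.54) and E2f1 (3.59) were higher, whereas Gdf15 (-6.72), Cd24a (-3.07), Jun (-1.68) and Lama3 (-3.21) were lower. A fit to these 6 libraries alone called 8595 genes without a block and 9146 with mouse as a block for the 3 pairs. Without wild-type anterior replicate 3 the count was 1532 and without ventral replicate 3 it was 1508. Luminal progenitor genes higher numbered 3, 3, 5 and 4 without anterior replicates 1 and 3 and ventral replicates 1 and 3. Unfolded protein genes lower numbered 4 without any of anterior replicates 1, 2 and 3 and ventral replicates 1 and 3.

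MYC PIN carried a growth and division programme beside signs of immune infiltration. Ribosome biogenesis genes such as Npm1 and Dkc1 were higher, as were mitotic kinases such as Ttk and Bub1, while some secretory products of the ventral lobe, such as Spink3, were lower. Antiviral genes induced by interferon and genes of cytotoxic T cells were higher. Some genes of the unfolded protein list, among them the chaperone gene Hspa5, were lower. Cdkn2a, which encodes tumour suppressors of the p16 and p19 family, was higher.

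MYC PIN differed from the wild-type ventral lobe in 1929 genes, 1162 higher and 767 lower. Cell cycle genes were called higher in 32 of 36, 35 adjusted over the list alone (camera adjusted p = 3e-34, adjusted p = 0.18 with an estimated correlation), with Ttk (log2 fold change 4.69), Nusap1 (4.19), Ccna2 (4.61) and Bub1 (4.69). Mki67 rose from 230 ± 44.2 to 4553 ± 3142 normalized counts (4.01). Ribosome biogenesis genes were higher in 19 of 36, 26 adjusted over the list alone (camera adjusted p = 6.8e-14, adjusted p = 0.28 with an estimated correlation), including Npm1 (2.14), Dkc1 (1.67), Nop58 (1.32) and Rrp9 (1.27). The count was 5 without MYC PIN replicate 1, 11 without wild-type ventral replicate 2 and 10 without ventral replicate 3. Chromatin genes of the Polycomb list had 4 of 17 higher, 6 adjusted over the list alone (camera adjusted p = 0.00071, adjusted p = 0.28 with an estimated correlation), and 1 and 2 without MYC PIN replicates 1 and 2. Uhrf1, which maintains DNA methylation, rose by 3.99.

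Interferon response genes were higher in MYC PIN in 25 of 27, 26 adjusted over the list alone (camera adjusted p = 4.2e-22, adjusted p = 0.2 with an estimated correlation), such as Rsad2 (6.56), Ifi44 (5.46), Zbp1 (5.10) and Oasl2 (5.19). T and NK cell genes were higher in 14 of 21, 17 adjusted over the list alone (camera adjusted p = 1.3e-13, adjusted p = 0.17 with an estimated correlation), including Cd8a (5.68), Lck (4.00), Il7r (3.51) and Cd8b1 (6.35). Without MYC PIN replicate 1, 13 interferon and 7 T and NK cell genes were called, and without ventral replicates 1, 2 and 3 the T and NK count was 9, 8 and 8. Macrophage genes were higher in 9 of 21 with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.2e-05, adjusted p = 0.41 with an estimated correlation), among them Ly6c2 (7.36) and Ms4a7 (3.08), and the count was 4 without ventral replicate 2 or MYC PIN replicate 1. B cell genes had 3 of 12 higher, 5 and 1 lower adjusted over the list alone (camera adjusted p = 0.0018, adjusted p = 0.28 with an estimated correlation), with Cd22 at 3.84. Cxcl11 (7.58), Oas3 (7.84) and Ly6c2 were among the largest increases of all genes, as were Htr5b (7.91), Slc15a1 (7.49) and Lingo3, which was at 0 in every wild-type ventral library and at 433 ± 60.9 in MYC PIN (at least 140-fold higher).

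Some secretory genes were lower in MYC PIN. Spink3 was at 1200041 ± 271245 normalized counts in wild type and 1080 ± 625 in MYC PIN (log2 fold change -10.25), and Ibsp (-9.42), Muc19 (-6.36), Spink5 (-6.26), Caln1 (-5.90), Gper1 (-5.85) and Mepe (-5.76) were lower. Androgen-responsive genes had 6 of 29 lower and 23 not called, with 7 lower adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.41 with an estimated correlation), including Fkbp5 (-2.31). That count was 3 without ventral replicate 3 and 2 without MYC PIN replicate 1. Unfolded protein genes were lower in 11 of 22, 14 adjusted over the list alone (camera adjusted p = 1.5e-09, adjusted p = 0.18 with an estimated correlation), such as Herpud1 (-1.83), Creld2 (-1.62), Hspa5 (-1.65) and Dnajb9 (-1.90). The count was 7, 6, 6 and 6 without ventral replicates 1, 2 and 3 and MYC PIN replicate 1. Smooth muscle genes had 5 of 16 lower, 11 adjusted over the list alone (camera adjusted p = 3.5e-06, adjusted p = 0.33 with an estimated correlation), but 0 without any of ventral replicates 1, 2 and 3 and MYC PIN replicate 1, and 3 without MYC PIN replicate 2. Senescence genes had 5 of 24 higher, 6 adjusted over the list alone (camera adjusted p = 0.0014, adjusted p = 0.33 with an estimated correlation), with Cdkn2a at 145 ± 56.4 against 3.64 ± 2.92 (5.08) and Il1a at 2.41, and 3 without MYC PIN replicate 1. Myc stood at 223 ± 30.6 against 622 ± 70.9 normalized counts (-1.48, adjusted p = 0.042), and its adjusted p was 0.083 to 0.13 without any 1 of the 6 libraries. The count of called genes was 1117, 884 and 1000 without ventral replicates 1, 2 and 3, and 766 without MYC PIN replicate 1.

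PTEN PIN was marked by progenitor-like luminal genes, among them Wfdc2 and Clu. Wfdc2 and genes for small proline-rich, trefoil and antimicrobial proteins were among the largest increases. Of 9 accessory gland carry-over genes, 2 rose too. Many NF-kB and senescence genes, such as Cxcl16, Cdkn1a and Cdkn2a, were higher. Ribosome biogenesis genes did not rise. The anterior-lobe peptidase inhibitor Serpina5 was close to absent.

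PTEN PIN differed from the wild-type anterior lobe in 2301 genes, 1543 higher and 758 lower. Age differed too, at 18 to 27 weeks against 12 in wild type. Far fewer genes were called without both libraries holding seminal vesicle transcripts, as given below. Luminal progenitor genes were higher in 16 of 18, 17 adjusted over the list alone (camera adjusted p = 1.9e-17, adjusted p = 0.1 with an estimated correlation), such as Clu (log2 fold change 7.89), Wfdc2 (9.10), Ly6d (7.07) and Lgals3 (5.13). Wfdc2 rose from 72.9 ± 24.9 to 51869 ± 38123 normalized counts. Sprr2a1 and Sprr2a2 (9.97 each), Tff3 (9.63), Reg3g (9.21), Ltf (9.15), Gsdmc4 (9.12) and Gsdmc3 (8.97) were the other largest increases. Krt8 (1.64), Krt19 (2.72) and Elf3 (3.75) were among 4 of 18 luminal genes called higher, 4 adjusted over the list alone (camera adjusted p = 0.15, adjusted p = 0.67 with an estimated correlation). Androgen-responsive genes had 7 of 29 higher and 1 lower, 9 and 2 adjusted over the list alone (camera adjusted p = 0.035, adjusted p = 0.55 with an estimated correlation), including Spink5 (6.41) and Fkbp5 (2.07). Nkx3-1 averaged 10999 against 53630 (-2.43, adjusted p = 0.079), Tgm4 201061 against 1862232 and Pbsn 86459 against 319720.

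Inflammatory genes rose in PTEN PIN. NF-kB genes were higher in 17 of 25, 20 adjusted over the list alone (camera adjusted p = 2.1e-11, adjusted p = 0.3 with an estimated correlation), with Cxcl16 (3.09), Nos2 (4.73) and Tnfaip3 (2.38). Saa1 was at 0 in every wild-type anterior library and 107 ± 12.3 in PTEN PIN (at least 36.1-fold higher). Senescence genes had 12 of 24 higher and 1 lower, 15 and 1 adjusted over the list alone (camera adjusted p = 5e-05, adjusted p = 0.3 with an estimated correlation), such as Cdkn1a (2.73), Plaur (3.12), Cdkn2a (3.33) and Cxcl2 (4.39). Interferon genes were higher in 18 of 27, 25 adjusted over the list alone (camera adjusted p = 5.1e-12, adjusted p = 0.33 with an estimated correlation), including Zbp1 (5.59) and Ifit1 (5.70). NF-kB and interferon counts were 10 or 11 without anterior replicate 1 or 3 or PTEN PIN replicate 1 or 3. Senescence counts were 7, 6 and 7 without anterior replicate 2, anterior replicate 3 and PTEN PIN replicate 3. Macrophage genes had 14 of 21 higher and 1 lower, 15 and 1 adjusted over the list alone (camera adjusted p = 8.9e-08, adjusted p = 0.3 with an estimated correlation), with Cd14 (3.15) and Ms4a7 (2.64). The number higher was 9 without any of anterior replicates 2 and 3 and PTEN PIN replicates 1, 2 and 3. Antigen presentation genes were higher in 9 of 18, 16 adjusted over the list alone (camera adjusted p = 4.8e-08, adjusted p = 0.3 with an estimated correlation), including H2-K1 (3.05), Psmb8 (3.35) and B2m (2.09). The count was 5 without anterior replicate 2, anterior replicate 3 or PTEN PIN replicate 3. T and NK cell genes had 7 of 21 higher, 13 adjusted over the list alone (camera adjusted p = 5.4e-06, adjusted p = 0.3 with an estimated correlation), with Cd8a at 5.47. The count was 4, 2, 4 and 2 without anterior replicates 2 and 3 and PTEN PIN replicates 2 and 3.

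Cell cycle genes in PTEN PIN had a median log2 fold change of 1.82. They were called higher in 19 of 36, 29 adjusted over the list alone (camera adjusted p = 9.7e-11, adjusted p = 0.43 with an estimated correlation), with Nusap1 (2.27) and E2f1 (1.62), but 2 were called without anterior replicate 2, anterior replicate 3 or PTEN PIN replicate 3 (medians 1.67, 1.57 and 1.45) and 7 without PTEN PIN replicate 2 (median 1.88). Ribosome biogenesis genes had 0 of 36 higher and 2 lower, 0 adjusted over the list alone (camera adjusted p = 0.0038 downward, adjusted p = 0.66 with an estimated correlation). Hypoxia and glycolysis genes had 7 of 22 higher, 9 adjusted over the list alone (camera adjusted p = 0.00036, adjusted p = 0.33 with an estimated correlation), including Hk2 (3.55), Egln3 (4.13) and Eno1 (2.10). The count was 4, 4, 3, 3 and 4 without anterior replicates 1, 2 and 3 and PTEN PIN replicates 1 and 2. Unfolded protein genes were lower in 10 of 22, 13 adjusted over the list alone (camera adjusted p = 1e-08, adjusted p = 0.3 with an estimated correlation), such as Chac1 (-4.16), Pdia6 (-1.52) and Atf4 (-1.48). The count was 6 without any of anterior replicates 1, 2 and 3 and PTEN PIN replicate 1. Serpina5 (-9.84), Gpr146 (-9.03), Prokr2 (-5.73), Mt3 (-4.72) and Cux2 (-4.70) were among the largest decreases, and Gper1 was at 0 in every PTEN PIN library (at least 145-fold lower). Pten averaged 5038 against 8760 normalized counts (-0.80, adjusted p = 0.0067). It was also lower in MYC PIN than in the ventral lobe, at 4539 ± 453 against 6859 ± 183 (-0.60, adjusted p = 0.043), though not called there without any 1 of the 6 libraries (adjusted p = 0.072 to 0.19). It stood at 4593 ± 1371 in BMPC PIN, where it was not called against MYC PIN (-0.02, adjusted p = 0.97). The count of called genes was 1514 and 1310 without anterior replicates 2 and 3, and 1383 and 1426 without PTEN PIN replicates 1 and 2.

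MYC PIN and PTEN PIN shared 372 genes called higher against their own lobes and 109 called lower, where independent calls would share 111 and 36. Another 80 were higher in PTEN PIN and lower in MYC PIN, and 18 the reverse. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson 0.30 and Spearman 0.25.

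The difference between both effects was tested directly, although lobe and age differ along with the model. Effects were compared as signed values. They were higher in MYC PIN for some ribosome biogenesis genes, and higher in PTEN PIN for most luminal progenitor genes and a few hypoxia and androgen-responsive genes. Fkbp5, the steroid receptor chaperone gene, moved in opposite directions in the models. Cdkn1a, the cell cycle inhibitor gene, had the larger effect in PTEN PIN. Its lesion levels were alike, at 426 ± 306 normalized counts in MYC PIN and 415 ± 100 in PTEN PIN. The wild-type ventral lobe stood at 354 ± 89.8 and the anterior lobe at 60.8 ± 6.59. Fkbp5 stood at 5165 ± 1980 in MYC PIN and 5970 ± 1395 in PTEN PIN, from 24329 ± 1007 and 1398 ± 18.8 in their lobes. For such genes the difference of effects includes the difference between the wild-type lobes.

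For 1199 genes the effects differed, 388 with a higher signed value in MYC PIN and 811 with a higher signed value in PTEN PIN. Ribosome biogenesis genes had 12 of 36 higher in MYC PIN, 26 adjusted over the list alone (camera adjusted p = 3.9e-16, adjusted p = 0.49 with an estimated correlation), including Ncl (difference of log2 fold changes 2.08), Npm1 (2.35) and Pa2g4 (1.55). Luminal progenitor genes had 11 of 18 higher in PTEN PIN, 16 adjusted over the list alone (camera adjusted p = 1.8e-13, adjusted p = 0.26 with an estimated correlation), such as Clu (-9.16), Psca (-8.57), Wfdc2 (-7.40) and Sox2 (-3.11). Androgen-responsive genes had 7 of 29 higher in PTEN PIN and 1 in MYC PIN, 9 and 1 adjusted over the list alone (camera adjusted p = 3.9e-05, adjusted p = 0.49 with an estimated correlation), including Fkbp5 (-4.38), Spink5 (-12.67) and Homer2 (-3.44). The number higher in PTEN PIN was 4 without ventral replicate 1, MYC PIN replicate 1 or PTEN PIN replicate 1 or 2. Hypoxia genes had 4 of 22 higher in PTEN PIN, 4 adjusted over the list alone (camera adjusted p = 8e-05, adjusted p = 0.49 with an estimated correlation), with Hk2 (-3.91) and Egln3 (-3.75). The count was 2 without any of anterior replicates 1, 2 and 3, ventral replicates 1, 2 and 3, MYC PIN replicates 2 and 3 and PTEN PIN replicates 1 and 2. Cell cycle genes had 2 of 36 higher in MYC PIN and 1 in PTEN PIN, 14 and 1 adjusted over the list alone (camera adjusted p = 2.9e-09, adjusted p = 0.83 with an estimated correlation), and 20 higher in MYC PIN without MYC PIN replicate 3, with Foxm1 at 3.12. Serpina5 (9.29), Muc19 (-14.98), Sval1 (-12.85), Ang3 (-12.73), Ang4 (-11.92), Spink3 (-10.70), Tff3 (-10.54), B2m (-2.84), Pigr (-9.89) and Cdkn1a (-2.65) were among the genes called. Serpina5 fell in PTEN PIN from 2038 ± 269 normalized counts and was already at 2.58 ± 1.56 in the wild-type ventral lobe. The count was 783 without ventral replicate 3, and 745 and 718 without PTEN PIN replicates 1 and 2.

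BMPC PIN combined progenitor and inflammatory genes with a division programme. Neutrophil genes such as S100a9 were higher, as was the acute phase gene Saa3. Androgen-responsive genes split, with Tgm4, Pbsn and the luminal transcription factor gene Nkx3-1 among those lower and others higher. Unfolded protein genes were lower in 21 of 22.

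BMPC PIN differed from the wild-type anterior lobe in 6690 genes, 3169 higher and 3521 lower, with batch and group confounded. Cell cycle genes were higher in 36 of 36, all 36 adjusted over the list alone (camera adjusted p = 7.3e-21, adjusted p = 0.24 with an estimated correlation), with Mki67 at 7044 ± 3571 against 292 ± 114 normalized counts (log2 fold change 4.54). Ribosome biogenesis genes had 23 of 36 higher, 27 adjusted over the list alone (camera adjusted p = 2.8e-08, adjusted p = 0.33 with an estimated correlation), such as Dkc1 (2.11), Npm1 (2.41) and Fbl (1.89), and 15 without BMPC PIN replicate 1. Luminal progenitor genes were higher in 18 of 18, all 18 adjusted over the list alone (camera adjusted p = 2.6e-10, adjusted p = 0.2 with an estimated correlation), with Lgals3 (5.94), Ly6d (6.82), Ltf (10.38) and Aqp3 (6.46). Interferon genes were higher in 25 of 27, 25 adjusted over the list alone (camera adjusted p = 5.9e-12, adjusted p = 0.3 with an estimated correlation), and NF-kB genes in 18 of 25, 18 adjusted over the list alone (camera adjusted p = 1.6e-09, adjusted p = 0.24 with an estimated correlation). Examples were Ifit1 (7.70), Rsad2 (6.54), Nos2 (7.47) and Cxcl2 (7.97). Neutrophil genes were higher in 14 of 18, 14 adjusted over the list alone (camera adjusted p = 2.8e-08, adjusted p = 0.24 with an estimated correlation), including S100a9 (8.76), S100a8 (7.79) and Cxcr2 (6.90). Senescence genes had 19 of 24 higher and 2 lower, 19 and 2 adjusted over the list alone (camera adjusted p = 4.9e-08, adjusted p = 0.18 with an estimated correlation), with Cdkn2a (7.35), Cdkn1a (4.38) and Il1a (5.99). Complement and acute phase genes had 11 of 19 higher and 2 lower, 12 and 2 adjusted over the list alone (camera adjusted p = 0.00035, adjusted p = 0.38 with an estimated correlation), with Saa3 at 8.13. The number lower was 1 without any of anterior replicates 1, 2 and 3 and BMPC PIN replicates 1 and 2.

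Hypoxia genes were higher in BMPC PIN in 16 of 22, 16 adjusted over the list alone (camera adjusted p = 7.9e-07, adjusted p = 0.24 with an estimated correlation), such as Egln3 (5.25), Hk2 (3.83) and Ankrd37 (4.55). Unfolded protein genes were lower in 21 of 22, 21 adjusted over the list alone (camera adjusted p = 3.1e-11, adjusted p = 0.18 with an estimated correlation), with Herpud1 (-3.18), Pdia6 (-3.53) and Creld2 (-2.67). Smooth muscle genes were lower in 13 of 16, 15 adjusted over the list alone (camera adjusted p = 4.5e-05, adjusted p = 0.33 with an estimated correlation), including Mylk (-2.40) and Myh11 (-2.69). Androgen-responsive genes split into 6 higher and 8 lower of 29, the same adjusted over the list alone (camera adjusted p = 0.23, adjusted p = 0.7 with an estimated correlation), with Nkx3-1 (-6.92), Tgm4 (-10.86), Pbsn (-10.11) and Gsdma (-6.26) among those lower. Reg3b (11.59), Lypd8 (10.54), Cxcl5 (10.18), Krt6a (9.76) and Krt13 (9.66) were the other largest increases. Glb1l3 (-14.32), Ren1 (-10.10) and Mt3 (-9.76) were among the largest decreases, and Tulp2 was at 0 in every BMPC PIN library against 989 ± 66.2 (at least 69.2-fold lower). Myc stood at 108 ± 63.4 against 1260 ± 78.0 (-3.71) and Hoxb13 at 2120 ± 1040 against 9485 ± 1286 (-2.31).

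PTEN PIN and BMPC PIN, both set against the same wild-type anterior libraries, shared 1202 genes called higher and 641 called lower. Simulated effects that shared only those controls gave 0 called in both, and 794 and 482 when as many top-ranked genes were taken. The fold changes correlated across genes at 0.71, against 0.50 in the simulations. Their covariance was 1.81 against a simulated 0.16. The difference of 1.65 estimates the covariance beyond noise in the shared controls.

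Against PTEN PIN, BMPC PIN showed a growth programme. Ribosome biogenesis and mitotic genes were higher, whereas 15 of 29 androgen-responsive genes, the homeobox gene Hoxb13 and the MHC light chain gene B2m were lower. The neutrophil calgranulin gene S100a9 was higher, as were Crnn and Sprr2d.

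The groups differed in 3895 genes, 1694 higher and 2201 lower in BMPC PIN, and the median log2 fold change of all genes was -0.135. Ribosome biogenesis genes were higher in 33 of 36, all 36 adjusted over the list alone (camera adjusted p = 1e-20, adjusted p = 0.26 with an estimated correlation), such as Pa2g4 (1.98), Npm1 (2.62), Dkc1 (2.23) and Nop58 (1.73), and 21 were called without BMPC PIN replicate 1. Cell cycle genes were higher in 33 of 36, all 36 adjusted over the list alone (camera adjusted p = 7.1e-20, adjusted p = 0.31 with an estimated correlation), including Rrm2 (2.73), Bub1 (3.47) and Ccna2 (3.20). Polycomb-list genes had 9 of 17 higher and 1 lower, 9 and 1 adjusted over the list alone (camera adjusted p = 0.00031, adjusted p = 0.28 with an estimated correlation), with Hmgb2 (2.54), Hells (2.43) and Cbx7 (-1.55). The number higher was 4, 3 and 3 without PTEN PIN replicate 1, PTEN PIN replicate 2 and BMPC PIN replicate 1. Neutrophil genes were higher in 11 of 18, 12 adjusted over the list alone (camera adjusted p = 2.9e-10, adjusted p = 0.26 with an estimated correlation), with S100a9 at 1116 ± 791 against 2.67 ± 1.17 normalized counts (7.92) and Cxcr2 (6.02). Senescence genes had 13 of 24 higher and 2 lower, 15 and 3 adjusted over the list alone (camera adjusted p = 6e-06, adjusted p = 0.26 with an estimated correlation), including Cdkn2a (4.03), Il1a (4.00) and Glb1 (-2.02). Reg1 (7.51), Il1f9 (7.18), Lgals2 (7.16), Otol1 (7.13), Crnn (7.02) and Saa3 (5.66) were higher, and Sprr2d was at 0 in every PTEN PIN library (at least 102-fold higher).

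Androgen-responsive genes were lower in BMPC PIN than in PTEN PIN in 15 of 29 and higher in 1, 16 and 1 adjusted over the list alone (camera adjusted p = 0.00025, adjusted p = 0.34 with an estimated correlation), with Msmb (-9.77), Azgp1 (-6.29), Nkx3-1 (-4.49) and Pbsn (-8.17). Unfolded protein genes were lower in 14 of 22, 15 adjusted over the list alone (camera adjusted p = 4.6e-07, adjusted p = 0.26 with an estimated correlation), including Herpud1 (-2.24) and Creld2 (-1.95). Antigen presentation genes had 3 of 18 lower, 3 adjusted over the list alone (camera adjusted p = 0.18, adjusted p = 0.8 with an estimated correlation), with B2m (-2.82) and H2-K1 (-1.88), and 7 lower without BMPC PIN replicate 2. Hoxb13 (-1.66), Glb1l3 (-10.23), Ren1 (-9.86), Clu (-3.03) and Myc (-2.17) were lower. The count of called genes was 2532 and 2437 without PTEN PIN replicates 1 and 2, and 6046 without BMPC PIN replicate 2. A fit to these 6 libraries alone called 564 genes, with 5 of 36 ribosome biogenesis and 14 of 36 cell cycle genes higher.

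Against MYC PIN, no member of the ribosome biogenesis or cell cycle lists was called higher in BMPC PIN, while hypoxia, neutrophil, senescence and NF-kB genes had members higher and androgen-responsive genes went both ways. Lobe of origin also differs in this comparison, and the ventral secretory genes Sbpl, Msmb and Sbp head the decreases. Skeletal muscle genes were also among the largest decreases. The cytotoxic effector genes Prf1 and Gzmb were lower, and Foxp3, which marks regulatory T cells, was higher. Prf1 averaged 8.17 ± 14.15 normalized counts in BMPC PIN, under the floor of 14.3 for that group, so the size of its change is uncertain.

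BMPC PIN and MYC PIN differed in 3110 genes, 1181 higher and 1929 lower. A fit to these groups alone called far fewer genes, and thinned reads also called fewer, as given below. Ribosome biogenesis genes had 0 of 36 higher and 1 lower, 0 adjusted over the list alone (camera adjusted p = 0.47, adjusted p = 0.96 with an estimated correlation), and 7 were higher without BMPC PIN replicate 2. Cell cycle genes had 0 of 36 called, 0 adjusted over the list alone (camera adjusted p = 0.0049 upward, adjusted p = 0.77 with an estimated correlation), and 5 and 3 higher without MYC PIN replicate 1 and BMPC PIN replicate 2. Hypoxia genes were higher in 14 of 22, 17 adjusted over the list alone (camera adjusted p = 2.4e-09, adjusted p = 0.15 with an estimated correlation), such as Egln3 (log2 fold change 3.34), Car9 (5.01), Pgk1 (1.88) and Ankrd37 (2.97), and 9 without MYC PIN replicate 3. Senescence genes had 13 of 24 higher and 1 lower, 17 and 1 adjusted over the list alone (camera adjusted p = 7.5e-09, adjusted p = 0.15 with an estimated correlation), with Mmp10 (4.49), Cxcl2 (6.04) and Cdkn1a (1.81). Neutrophil genes were higher in 11 of 18, 12 adjusted over the list alone (camera adjusted p = 4e-09, adjusted p = 0.36 with an estimated correlation), including Cxcr2 (6.58) and Trem1 (5.37). Luminal progenitor genes had 8 of 18 higher, 12 adjusted over the list alone (camera adjusted p = 1.4e-05, adjusted p = 0.61 with an estimated correlation), with Aqp3 (5.11) and Lypd3 (3.93). The count was 5, 4 and 5 without MYC PIN replicates 2 and 3 and BMPC PIN replicate 2. T and NK cell genes had 7 of 21 lower and 1 higher, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0088, adjusted p = 0.65 with an estimated correlation), with Prf1 (-4.20), Gzmb (-2.70) and Foxp3 (3.23). The number lower was 3, 4 and 4 without MYC PIN replicates 1 and 2 and BMPC PIN replicate 3. NF-kB genes had 9 of 25 higher, 13 adjusted over the list alone (camera adjusted p = 8.4e-07, adjusted p = 0.61 with an estimated correlation), and 5 without MYC PIN replicate 2 or 3. Androgen-responsive genes had 13 of 29 lower and 4 higher, 15 and 4 adjusted over the list alone (camera adjusted p = 0.0049, adjusted p = 0.65 with an estimated correlation). The number higher was 2 without any of MYC PIN replicates 1, 2 and 3 and BMPC PIN replicates 2 and 3. Krt13 (10.00), Reg3b (9.74), Onecut2 (9.28), Olfm4 (8.90) and Me1 (3.69) were higher. Sbp (-12.33), Sbpl (-13.62), Msmb (-12.42), Wfdc3 (-10.67), Hoxb13 (-2.89) and Nkx3-1 (-3.97) were lower, and Syt10 was at 0 in every BMPC PIN library (at least 62.4-fold lower). Genes of skeletal muscle, fat and blood carried over from other tissue had 6 of 15 lower, 6 adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.65 with an estimated correlation). The count was 3 without MYC PIN replicate 2 or 3. The camera adjusted p was 0.072 and 0.07 without MYC PIN replicate 3 and BMPC PIN replicate 2. Myh1 stood at 2883 ± 2520 normalized counts in MYC PIN (-9.26), and Myh4 was at 0 in every BMPC PIN library (at least 437-fold lower). Without MYC PIN replicates 2 and 3 in turn, 1805 and 1639 genes were called.

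**Figure D2:**
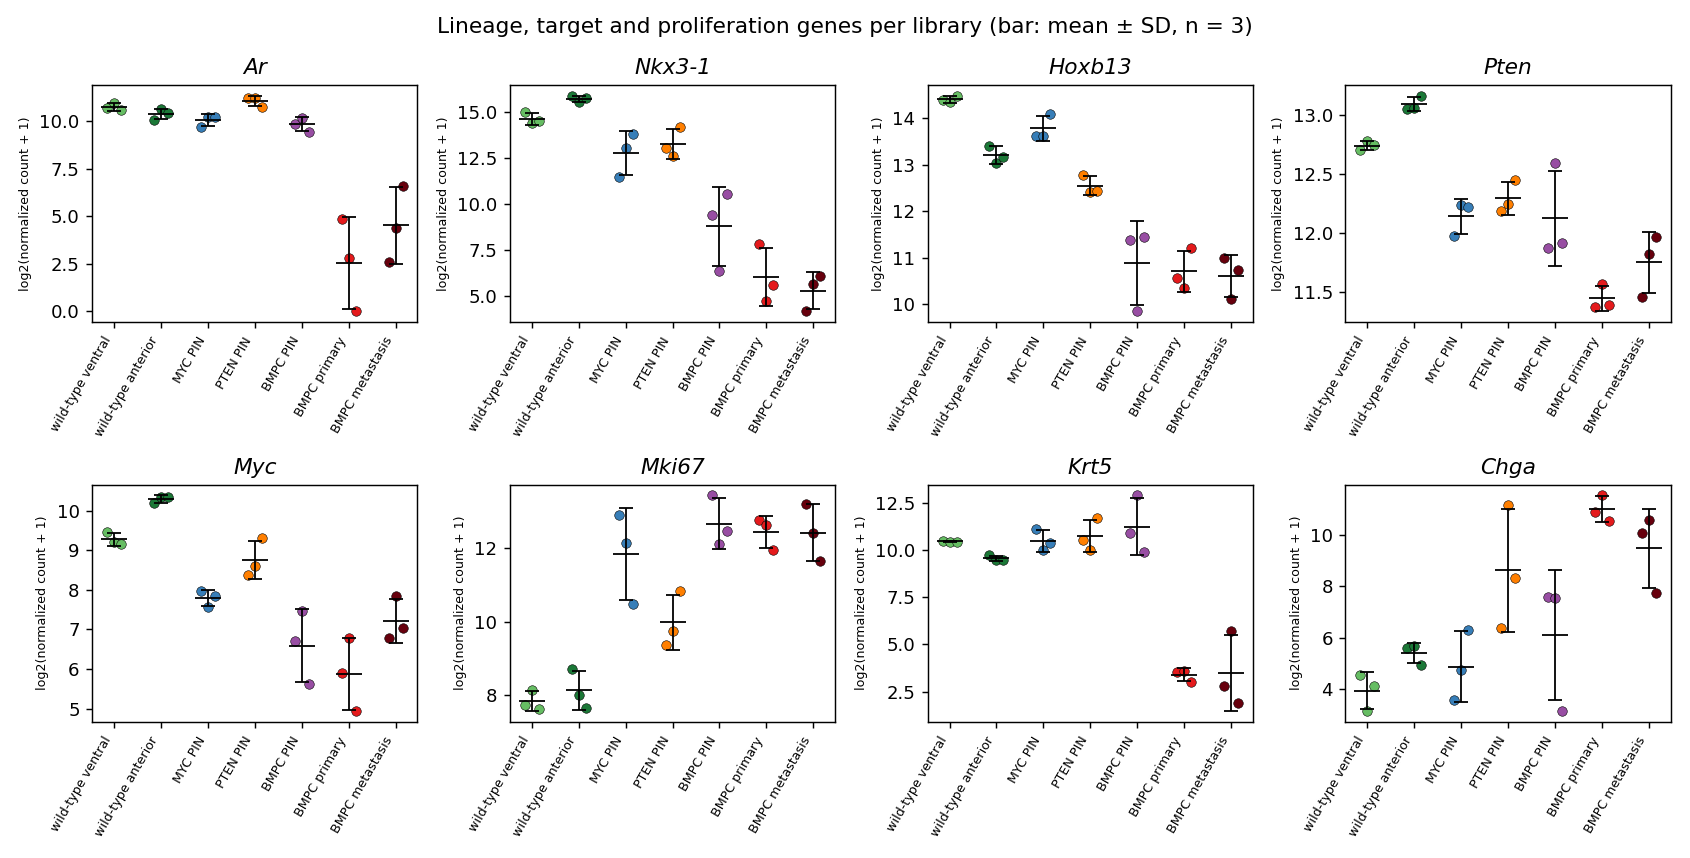
Log2(normalized count + 1) of 8 panel genes, with 1 point per library and bars for mean ± SD of 3 libraries per group. Ar averages 934 normalized counts in BMPC PIN and 11.2 in primaries, and Krt5 3466 and 9.66.

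In BMPC primaries many luminal and basal genes were lower than in BMPC PIN. The androgen receptor gene Ar, the basal keratin gene Krt5 and the basal regulator Trp63 fell to low levels, while neuronal and neuroendocrine genes such as Insm1, Syp and Nefl rose. Interferon-induced genes and MHC class I genes were lower. Mki67 was not called. The homeobox gene Tlx1 and the scaffold gene Dlgap3 were among the largest increases.

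Primaries differed from BMPC PIN in 6262 genes, 3330 higher and 2932 lower, again with batch and group confounded. Age differed as well, at 18 to 25 weeks against 12 in BMPC PIN. A fit to these groups alone called fewer genes, as given below. Interferon genes were lower in 27 of 27, all 27 adjusted over the list alone (camera adjusted p = 9.9e-16, adjusted p = 0.37 with an estimated correlation), with Ifit3 (log2 fold change -8.10), Ifit2 (-5.22) and Gbp4 (-5.09). Antigen presentation genes were lower in 16 of 18, 16 adjusted over the list alone (camera adjusted p = 7e-07, adjusted p = 0.37 with an estimated correlation), including B2m (-3.63), Psmb9 (-4.01) and Ciita (-4.44). NF-kB genes were lower in 20 of 25, 20 adjusted over the list alone (camera adjusted p = 7e-07, adjusted p = 0.37 with an estimated correlation), such as Birc3 (-3.27) and Tnf (-3.98). T and NK cell genes were lower in 10 of 21, 10 adjusted over the list alone (camera adjusted p = 6.3e-05, adjusted p = 0.37 with an estimated correlation), with Cd3e (-5.21) and Gzmb (-4.73). Complement genes were lower in 14 of 19, 17 adjusted over the list alone (camera adjusted p = 6.3e-06, adjusted p = 0.37 with an estimated correlation), including Cfb (-4.12). Neutrophil genes were lower in 8 of 18, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.01, adjusted p = 0.62 with an estimated correlation), and 5 and 3 without BMPC PIN replicate 2 and primary replicate 6.

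Lineage genes were called as well. Luminal progenitor genes were lower in primaries in 15 of 18, with 17 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.4e-08, adjusted p = 0.37 with an estimated correlation), such as Tacstd2 (-8.11), Psca (-7.99) and Ly6a (-6.19). Basal genes were lower in 12 of 16, with 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 7e-07, adjusted p = 0.37 with an estimated correlation), with Krt15 (-8.83), Krt5 (-7.84), Col17a1 (-7.71) and Trp63 (-7.14). Luminal genes had 9 of 18 lower and 2 higher, 12 and 3 adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.37 with an estimated correlation), including Ar (-7.29), Foxa1 (-2.63) and Dpp4 (-5.15), whereas Krt8 was higher by 1.06. Neuroendocrine genes were higher in 14 of 21, 16 adjusted over the list alone (camera adjusted p = 2.2e-05, adjusted p = 0.37 with an estimated correlation), with Insm1 (6.28), Syp (5.44), Scg5 (6.23) and Scg3 (7.31), and Chga rose from 128 ± 104 to 2136 ± 757 normalized counts (4.90). Smooth muscle genes were lower in 11 of 16, 12 adjusted over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.37 with an estimated correlation), such as Myh11 (-3.56). Cell cycle genes had 1 of 36 higher, 1 adjusted over the list alone (camera adjusted p = 0.74, adjusted p = 0.95 with an estimated correlation). Nefl (10.99), Nell2 (9.96) and Dlgap3 (9.90) were among the largest increases, and Tlx1 (at least 105-fold), Fam155a (at least 82.4-fold), Hpca (at least 132-fold) and Slc44a5 (at least 168-fold) were higher than a BMPC PIN group at 0. Reg3b (-10.81), Lypd8 (-10.45), Gpr128 (-10.04), Tff3 (-9.16) and Otol1 (-8.79) were among the largest decreases.

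Primaries and PTEN PIN shared a batch, so their contrast does not carry that confounder, and their ages overlap, at 18 to 25 and 18 to 27 weeks, though genotype and lesion stage differ. Primaries expressed a chemosensory or tuft-like set of genes, including the cation channel gene Trpm5 and the taste transduction gene Gng13. Many luminal and androgen-responsive genes, keratins of the basal layer and MHC class I genes were lower, and growth genes were higher. Smooth muscle genes were lower, while fibroblast genes went both ways and no endothelial gene was called lower.

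The contrast called 8016 genes, 3964 higher and 4052 lower in primaries. Ribosome biogenesis genes were higher in 35 of 36, 35 adjusted over the list alone (camera adjusted p = 4e-12, adjusted p = 0.25 with an estimated correlation), with Dkc1 (log2 fold change 2.46) and Nop56 (2.90), and cell cycle genes in 36 of 36, all 36 adjusted over the list alone (camera adjusted p = 2e-10, adjusted p = 0.36 with an estimated correlation), with Top2a (2.88) and E2f1 (2.37). Polycomb-list genes had 14 of 17 higher, 14 adjusted over the list alone (camera adjusted p = 0.00023, adjusted p = 0.25 with an estimated correlation), including Dnmt3b (3.48), Hmga1 (3.22) and Cbx2 (1.94). Neuroendocrine genes were higher in 13 of 21, 13 adjusted over the list alone (camera adjusted p = 0.00013, adjusted p = 0.25 with an estimated correlation), such as Insm1 (7.05), Dll3 (7.38) and Sox11 (7.93). Hypoxia genes were higher in 15 of 22, 16 adjusted over the list alone (camera adjusted p = 0.00013, adjusted p = 0.25 with an estimated correlation), with Pfkp (2.49). Oxidative phosphorylation genes had 12 of 24 higher, 15 adjusted over the list alone (camera adjusted p = 4e-04, adjusted p = 0.47 with an estimated correlation), with Ndufs2 (1.02), and 6 without PTEN PIN replicate 3. Sterol and fatty acid genes had 13 of 23 higher and 2 lower, 13 and 2 adjusted over the list alone (camera adjusted p = 0.0072, adjusted p = 0.53 with an estimated correlation), including Elovl6 (4.03), Hmgcr (1.71) and Me1 (-2.01). Sh2d7 (11.55), Trpm5 (11.03), Gng13 (10.91), Ovol3 (10.48), Rgs13 (10.46), Gnb3 (10.20) and Gsg1l (10.06) led all increases.

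Androgen-responsive genes were lower in primaries in 17 of 29 and higher in 2, the same adjusted over the list alone (camera adjusted p = 0.00013, adjusted p = 0.25 with an estimated correlation), with Slc45a3 (-4.47), Nkx3-1 (-7.21) and Pbsn (-8.24). Luminal genes were lower in 13 of 18, 13 adjusted over the list alone (camera adjusted p = 1.6e-05, adjusted p = 0.25 with an estimated correlation), including Ar (-8.52), Foxa1 (-3.59) and Hoxb13 (-1.84). Basal genes were lower in 10 of 16, 10 adjusted over the list alone (camera adjusted p = 0.00024, adjusted p = 0.36 with an estimated correlation), with Krt15 (-9.80) and Krt5 (-7.35). Luminal progenitor genes were lower in 15 of 18, 15 adjusted over the list alone (camera adjusted p = 3.3e-06, adjusted p = 0.25 with an estimated correlation), such as Psca (-9.62) and Clu (-8.66). Antigen presentation genes were lower in 16 of 18, 16 adjusted over the list alone (camera adjusted p = 4.6e-07, adjusted p = 0.25 with an estimated correlation), with B2m (-6.45) and H2-K1 (-3.71), and interferon genes in 26 of 27, 26 adjusted over the list alone (camera adjusted p = 5.8e-08, adjusted p = 0.36 with an estimated correlation), with Stat2 (-3.51). T and NK cell genes were lower in 14 of 21, 15 adjusted over the list alone (camera adjusted p = 0.00052, adjusted p = 0.35 with an estimated correlation), and 7 without PTEN PIN replicate 3. Smooth muscle genes were lower in 14 of 16, 14 adjusted over the list alone (camera adjusted p = 3.6e-07, adjusted p = 0.25 with an estimated correlation), including Cnn1 (-6.79). Fibroblast genes had 5 of 22 higher and 6 lower, 8 and 6 adjusted over the list alone (median 0.44; camera adjusted p = 0.78, adjusted p = 0.99 with an estimated correlation). The number higher was 2 without any of PTEN PIN replicates 1 and 2 and primary replicates 4 and 5, and 8 without primary replicate 6. The number lower was 10 without primary replicate 4. Endothelial genes had 4 of 16 higher and 0 lower, 2 and 0 adjusted over the list alone (median 0.75; camera adjusted p = 0.1, adjusted p = 0.68 with an estimated correlation). The number higher was 2 without any of PTEN PIN replicates 1 and 2 and primary replicates 4 and 5. The camera adjusted p was 0.039 and 0.036 without PTEN PIN replicate 3 and primary replicate 6. Tff3 (-11.29), Gsdmc2 (-10.99), Fcgbp (-10.42), Fmo3 (-9.87) and Sult1c2 (-9.84) were among the largest decreases. Pten stood at 2791 ± 213 against 5038 ± 492 normalized counts (-0.85).

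A list of tuft cell genes was written only after values of about 26 of its genes had been seen, with Sox9, Ascl2 and Krt18 seen and left out, so its counts are no independent evidence. It had 34 of 36 tested genes higher and 2 lower in primaries than in PTEN PIN, with a median log2 fold change of 5.54 (camera unadjusted p = 4e-19, and unadjusted p = 0.003 with an estimated correlation). Fut2 and Tmem176a were the 2 lower. Pou2f3, which encodes the transcription factor that specifies tuft cells, stood at 4336 ± 310 against 164 ± 51.5 normalized counts and at 33.2 ± 10.7 in BMPC PIN. Trpm5 stood at 17054 ± 2177 against 7.93 ± 4.14, and Sh2d7, Avil, Bmx, Dclk1 and Spib were also higher. Against BMPC PIN 33 of 36 were higher in primaries (median 5.80, or 5.31 with genes at 0 set to the floor; camera unadjusted p = 9.8e-21, and unadjusted p = 0.0022 with an estimated correlation), and between metastases and primaries 0 were called (median -0.55; camera unadjusted p = 0.002 downward, and unadjusted p = 0.24 with an estimated correlation).

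**Figure D3:**
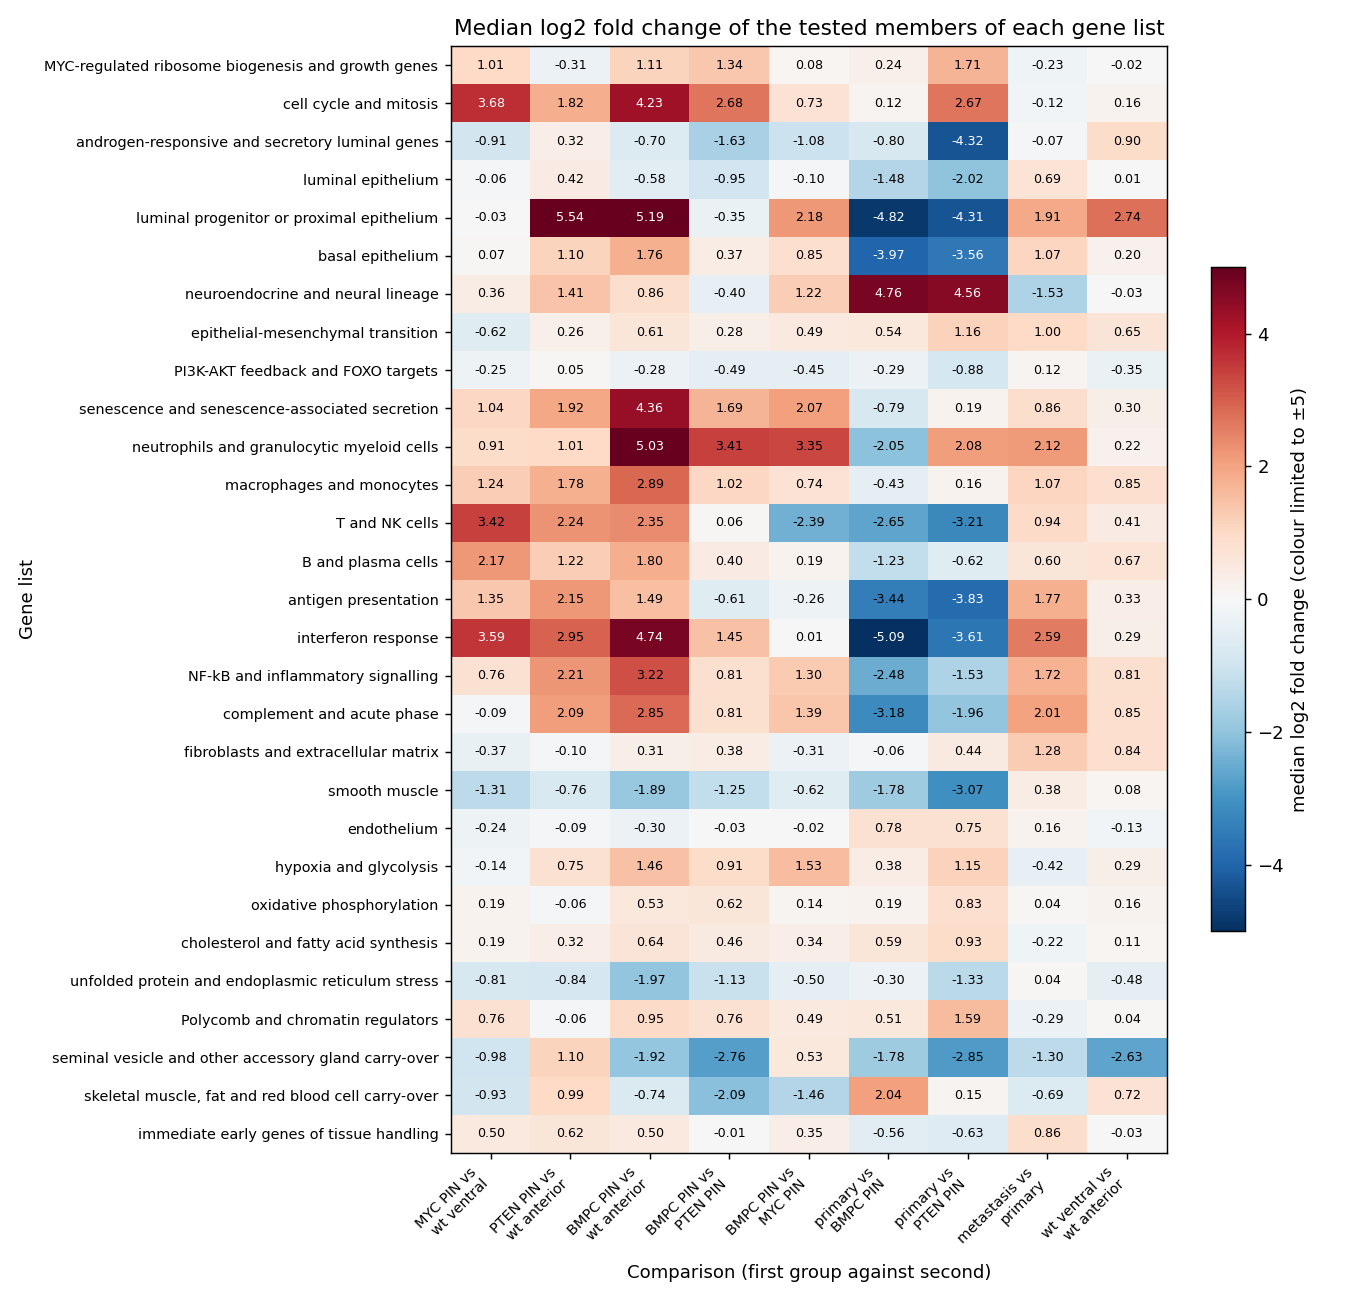
Median log2 fold change of the tested members of each of the 29 gene lists (vertical) in 9 comparisons (horizontal, first group against second), with the value printed in each cell. Interferon genes have medians of -5.09 in primaries against BMPC PIN and 2.59 in metastases against primaries.

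The contrasts of BMPC PIN and of primaries with the same PTEN PIN libraries shared 1197 genes called higher and 1238 called lower, against 0 in simulations that shared only those controls and 988 and 1248 when as many top-ranked genes were taken. Across genes the fold changes correlated at 0.35, against 0.50 in the simulations, and their covariance was 1.06 against a simulated 0.18, a difference of 0.88.

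Few genes were called between metastases and primaries, and Ar was low at both sites. The desmosomal cadherin gene Dsc1 and the peptidase gene Dpep1 were higher, and Cdkn1c, which encodes a cell cycle inhibitor, and the axon maintenance gene Nmnat2 were lower. Interferon and antigen presentation genes leaned higher as groups, as did NF-kB, neutrophil, complement, macrophage, luminal progenitor and fibroblast genes, without any member called by limma over all genes and only with the preset correlation in camera. The preset correlation also called senescence, luminal, basal, mesenchymal transition, T and NK cell and tissue-handling immediate early genes upward (camera adjusted p = 0.0022 to 0.022). With an estimated correlation their adjusted p was 0.35 to 0.67.

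The comparison called 34 genes, 20 higher and 14 lower, and 2494 had an unadjusted p under 0.05. Dsc1 (log2 fold change 5.23), Dpep1 (3.80), Serpinb5 (2.96), Tspan6 (2.88), Kctd14 (2.88) and Gstt1 (2.85) were called higher, and Nmnat2 (-3.69), Cyfip2 (-3.28), Fat3 (-2.80), Cdkn1c (-2.78), Tnik (-2.47) and Ptprt (-3.18) lower. Nmnat2 stood at 28.6 ± 12.6 normalized counts in metastases and 381 ± 178 in primaries. None of these 12 was called without metastasis replicate 7 or without primary replicate 6. Leaving out 1 library gave 263, 166 and 4 called genes without primary replicates 4, 5 and 6, and 717, 9 and 0 without metastasis replicates 5, 6 and 7. With mouse number as a block, 0 genes were called by limma and 426 had an unadjusted p under 0.05, while DESeq2 and edgeR without a block called 886 and 10.

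No list member was called over all genes, by limma. Interferon genes had 0 of 27 called but 26 higher adjusted over the list alone (camera adjusted p = 1.2e-20, adjusted p = 0.24 with an estimated correlation), with Isg15 at 4.58 and Mx1 at 3.28. Antigen presentation genes had 0 of 18 called and 12 higher adjusted over the list alone (camera adjusted p = 2.4e-09, adjusted p = 0.24 with an estimated correlation), with Psmb9 at 2.62. NF-kB genes had 0 of 25 called and 15 higher adjusted over the list alone (camera adjusted p = 4.3e-11, adjusted p = 0.24 with an estimated correlation), and neutrophil genes 0 of 18 and 12 adjusted over the list alone (camera adjusted p = 8.5e-09, adjusted p = 0.24 with an estimated correlation). Without metastasis replicate 5, 16 interferon, 6 antigen presentation, 6 NF-kB and 5 neutrophil genes were called, and 6 interferon genes without primary replicate 4 or 5, and 2 and 3 NF-kB genes without primary replicates 4 and 5 and 1 neutrophil gene without either, and 2 and 1 antigen presentation genes without primary replicates 4 and 5. Complement genes had 0 of 19 called and 12 higher adjusted over the list alone (camera adjusted p = 8.5e-09, adjusted p = 0.24 with an estimated correlation), and macrophage genes 0 of 21 and 3 (camera adjusted p = 3.5e-08, adjusted p = 0.24 with an estimated correlation). Luminal progenitor genes had 0 of 18 and 4 (camera adjusted p = 1.7e-06, adjusted p = 0.24 with an estimated correlation) and fibroblast genes 0 of 22 and 0 (camera adjusted p = 0.00021, adjusted p = 0.58 with an estimated correlation). Without metastasis replicate 5, 6 complement genes, 4 macrophage genes, 3 luminal progenitor genes and 1 fibroblast gene were called. Without primary replicate 4, 3 complement genes and 1 luminal progenitor gene were called, and without primary replicate 5, 1 luminal progenitor gene. Without primary replicate 6 the camera adjusted p of fibroblast genes was 0.099. Neuroendocrine genes had 0 of 21 called and 3 lower adjusted over the list alone (camera adjusted p = 1.6e-05 downward, adjusted p = 0.24 with an estimated correlation), with Pcsk2 at -4.40, and 1 was called lower without primary replicate 4 or metastasis replicate 5. Ribosome biogenesis genes had 0 of 36 called and 0 adjusted over the list alone (camera adjusted p = 0.011 downward, adjusted p = 0.68 with an estimated correlation). With the mouse block its camera adjusted p was 0.41. Ar stood at 40.3 ± 49.1 and 11.2 ± 14.5 normalized counts (1.97, adjusted p = 0.3).

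Across all groups, Trp53 averaged 333 ± 20.4 normalized counts in wild-type ventral lobe, 393 ± 37.3 in anterior lobe, 763 ± 198 in MYC PIN, 586 ± 99.6 in PTEN PIN, 1935 ± 832 in BMPC PIN, 936 ± 277 in primaries and 971 ± 452 in metastases. Ptprc, the pan-leukocyte gene, averaged 237 ± 26.7, 187 ± 15.2, 1505 ± 642, 730 ± 316, 1649 ± 774, 789 ± 455 and 1550 ± 1098 in the same order. Vim averaged 3320 ± 594, 2100 ± 292, 2534 ± 429, 2725 ± 1124, 3988 ± 4180, 6433 ± 3115 and 9647 ± 2885 and was not called in any of the 10 comparisons. With the estimated correlation, camera called none of the 29 fixed lists in any comparison.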

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

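Of the tests below, the difference of the MYC PIN and PTEN PIN effects and its list tests were planned before the data were seen, those on depth and transcript length were added after the data but before their own results were seen, and the others were chosen after the results were seen. A difference between groups, tested directly as the difference of the MYC PIN and PTEN PIN effects, drew attention to 1199 genes. The same test across lists gave medians of 1.36 for ribosome biogenesis, 1.82 for cell cycle, -1.51 for androgen-responsive, -4.74 for luminal progenitor, 1.14 for T and NK cell (1.03 with genes at 0 set to the floor), -1.3 for NF-kB, -1.25 for complement (-1.07 at the floor), -0.96 for hypoxia and 0.47 for Polycomb genes. Positive values are higher in MYC PIN. Lobe and age differ along with the model, at 10 to 15 weeks for MYC PIN and 18 to 27 for PTEN PIN against 12 in both wild types, so the difference is one of model, lobe and age together. With the estimated correlation camera called none of these lists (adjusted p = 0.26 to 0.84). With the preset correlation it lost its call of the complement list (adjusted p = 0.056) without MYC PIN replicate 2 and of the Polycomb list (adjusted p = 0.053) without MYC PIN replicate 1. The T and NK cell list lost it as well, with an adjusted p of up to 0.17.

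Ribosome biogenesis genes were higher in BMPC PIN than in PTEN PIN in 33 of 36, although camera with the estimated correlation did not call the list (adjusted p = 0.26). Lower depth of the BMPC PIN libraries is an unlikely candidate explanation, since 32 were still called after thinning all libraries to the shallowest. A trend with transcript length is also unlikely, since 32 were called after its removal. Both fits kept the shared spread of all 21 libraries, which understates that of BMPC PIN. As given above, a fit to these groups alone called far fewer members, and leaving out BMPC PIN replicate 1 also lowered the count. The checks therefore bear on depth and length only. The second sequencing batch remains open, because batch and group are confounded and cannot be told apart. Age, 12 weeks in BMPC PIN and 18 to 27 in PTEN PIN, stays open as well. In primaries against PTEN PIN, both from the first batch, 35 of 36 were higher.

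Tuft cell genes were higher in primaries than in PTEN PIN, on a list written after values had been seen. A lower share of luminal cells could raise other cell types too, but the basal list had a median of -3.56, smooth muscle -3.07, T and NK cells -3.21 and macrophages 0.16. Immune cells carrying tuft genes stay open. The highest immune median was 2.08 (neutrophils, 1.14 at the floor), but the tuft median, 5.54, is of chosen genes. In metastases 31 of 36 tuft genes lay above every PTEN PIN library, but the genes had been chosen after values were seen, so this count decides nothing and a programme of BMPC tumours at both sites stays open. Bulk values do not show which cells express the genes.

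Interferon genes leaned higher in metastases than in primaries, with a median of 2.59. Limma called 0 of 27 members over all genes and 26 adjusted over the list alone, and camera with the estimated correlation did not call the list (adjusted p = 0.24). Lymphocytes of the lymph node were a weak candidate by size, since the T and NK cell median was 0.94 and the B cell median 0.6. Cd79a, Cd3e and Ms4a1 reached at most 16.5, 13.8 and 16.5 normalized counts in metastases, but only 3.5, 0.6 and 1.7 in primaries. Camera with the preset correlation also called the T and NK cell list upward (adjusted p = 0.022, adjusted p = 0.58 with an estimated correlation). Lymphocyte markers thus leaned higher too, and a share of the interferon rise from lymphocytes stays open. A single library may set the size but not the direction, since the lowest median without 1 library was 1.77, without primary replicate 6. That library stood apart, with a median log2 value of 4.67 for interferon genes against 7.16 and 7.62 in the other primaries and with 7.18% of its counts in Rn45s. The pairs differed as well, with a median of 0.4 in mouse 5 and 6.11 in mouse 6. Medians were also above 0 for complement (2.01), neutrophil (2.12), luminal progenitor (1.91), fibroblast (1.28) and macrophage genes (1.07), and without primary replicate 6 those of the last 4 were 1.44, 0.73, 0.27 and 0.79. A wider difference in the cells of these tumours therefore stays open. Apart from lymphocytes as a source, no biological explanation was tested.

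Regrouping the libraries of each comparison into all 10 possible splits of 3 against 3 gave too few splits for a share under 0.05. The true grouping ranked 1 of 10 in MYC PIN against ventral lobe, PTEN PIN against anterior lobe and BMPC PIN against anterior lobe, where the highest other count was 0. It ranked 1 with a highest other count of 8 in BMPC PIN against PTEN PIN, 1240 in BMPC PIN against MYC PIN, 816 in primaries against BMPC PIN, 4 in primaries against PTEN PIN and 1 between the lobes. It ranked 2 in metastases against primaries, where 34 genes were called and another split gave 54. The difference of the MYC and PTEN effects ranked 1 of 100, with a highest other count of 236. Those splits shuffled the libraries of both lobes and both lesions together, which also broke up the lobe and lesion differences. That rank therefore cannot isolate the difference of effects.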

How the results depend on the processing

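All alternatives were planned before the values were seen except thinning, length correction, leaving out both libraries with seminal vesicle transcripts and leaving 1 library out of the list tests. No named gene called in the main fit changed sign under any setting. With library weights, 1 named-gene result not called in the main fit was called with the opposite sign. Signs of genes called in neither fit were not compared. Each count not given below stayed within 1.5 times its value under that setting, and the cause was not tested for the changes listed. The shared spread of all 21 libraries understates that of BMPC PIN, whose median within-group SD was 0.69 on the log2 scale, and overstates that of the wild types, at 0.14 and 0.17. In simulations with 2-fold changes limma recovered 2% in BMPC PIN against PTEN PIN, 10% in MYC PIN and 10% in metastases, and at 4-fold 59%, 55% and 68%. False calls made up 18.7%, 4.4% and 9.3% for limma and 15.7%, 22.4% and 24.4% for DESeq2. The simulations gave all libraries the same dispersion per gene, so they left out the unequal spread of the groups. They also changed far fewer genes than most comparisons called, so these rates need not hold for the real comparisons. Of 1400 named-gene results, 1318 kept their call with edgeR, 1249 with DESeq2, 1375 with TMM factors, 1059 with only the groups compared and 1010 with a minimum log2 fold change of 1.

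With only the groups compared in the fit, the counts were 5778 for MYC PIN, 7151 for PTEN PIN, 8595 between lobes, 5374 for the difference, 4227 for BMPC PIN against anterior lobe, 564 against PTEN PIN, 390 against MYC PIN, 2315 for primaries against BMPC PIN and 0 for metastases. With library weights they were 8039 for MYC PIN, 10172 for PTEN PIN, 9806 between lobes, 8424 for the difference and 4 for metastases. With a minimum log2 fold change of 1, which by construction calls fewer genes, they were 288, 545, 587 and 259 in the same order, 2212, 431 and 626 for BMPC PIN against anterior lobe, PTEN PIN and MYC PIN, 2633 and 3150 for primaries against BMPC PIN and PTEN PIN, and 0 for metastases. DESeq2 gave 3143 for MYC PIN, 3708 for PTEN PIN, 2326 for the difference and 886 for metastases. Metastases gave 10 with edgeR, 19 and 133 with pseudocounts of 0.5 and 5, and 77 with no filter. Thinned reads gave 1927 for BMPC PIN against MYC PIN, and PTEN PIN without both libraries holding seminal vesicle transcripts gave 902.

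Pairing was real only between lobes and between tumours of the same mouse. With the replicate number as a block the counts were 9146 between lobes and 0 for metastases, and with animal as a random block metastases gave 9. Blocking on numbers that pair no animals gave 4391 for MYC PIN, 6253 for PTEN PIN, 3874, 22 and 154 for BMPC PIN against anterior lobe, PTEN PIN and MYC PIN, and 5311 for the difference. No paired analysis was possible for primaries against BMPC PIN or PTEN PIN because their replicate numbers do not overlap. In camera the block ended the call of ribosome biogenesis (adjusted p = 0.41), mesenchymal transition (0.056) and hypoxia (0.45) for metastases. It brought smooth muscle for metastases, and mesenchymal transition (0.042), macrophages (0.0021), antigen presentation (0.044), complement (0.0051) and fibroblasts (0.0015) between lobes, and changed no other list call of these pairs.

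Leaving out 1 library gave 766 to 1630 for MYC PIN, 1310 to 1868 for PTEN PIN, 1508 to 1759 between lobes, 718 to 1218 for the difference, 5323 to 7689 for BMPC PIN against anterior lobe, 2437 to 6046 against PTEN PIN, 1639 to 4129 against MYC PIN, 5183 to 6493 for primaries against BMPC PIN, 6774 to 7439 against PTEN PIN and 0 to 717 for metastases.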

Other observations

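Some single genes, chosen after their values were seen, are given here as values. Primaries expressed the neural cadherin gene Cdh2 at 6343 ± 2526 normalized counts against 46.0 ± 39.8 in BMPC PIN, and Neurod1, which encodes a neuronal transcription factor, at 290 ± 295 against 2.04 ± 3.54. Ascl1, another neuronal factor gene, stood at 76.9 ± 66.3 and 80.4 ± 51.6. The tuft cell cytokine gene Il25 stood at 58.4 ± 19.4 in primaries and at 0 in every BMPC PIN library.

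Another 3 genes were chosen in the same way. Spp1, which encodes osteopontin, averaged 145 ± 25.2 in PTEN PIN, 2839 ± 2645 in BMPC PIN, 5750 ± 4626 in primaries and 14441 ± 3770 in metastases. Mmp12, a macrophage elastase gene, averaged 30.4 ± 7.15, 898 ± 750, 2285 ± 1810 and 1953 ± 937 in the same groups, and Arg1, an arginase gene of myeloid cells, averaged 595 ± 298, 5643 ± 1967, 929 ± 765 and 2485 ± 709.

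Xist stood at 424.8 and 26.2 normalized counts in primary replicates 5 and 6, and at 265.2, 393.8 and 101.9 in metastasis replicates 5, 6 and 7, with 4.1 in primary replicate 4, 0 in every BMPC PIN library and at most 6.2 elsewhere. Ddx3y, on the Y chromosome, was between 1104.6 and 2941.2 in all 21 libraries. Svs2, a seminal vesicle gene, averaged 23639 ± 40889 in wild-type anterior lobe and 11025 ± 18898 in PTEN PIN. Ckm, a skeletal muscle gene, averaged 2110 ± 1827 in MYC PIN against 122 ± 9.04 in wild-type ventral lobe. Rn45s, a ribosomal RNA precursor, made up 7.18% of primary replicate 6, 5.45% and 5.05% of metastasis replicates 7 and 6 and 3.06% of BMPC PIN replicate 3. A single gene, 9530053A07Rik, made up 32.7% to 37.3% of the wild-type anterior libraries.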
